A study of Mus musculus with 40 samples.

How the data were processed

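Macrophages elicited in the mouse peritoneum with thioglycollate broth, an irritant that draws monocytes into the cavity, were studied in C57BL6/J and BALBc/J, a pair of inbred strains. Cells were left without treatment or given 100 ng/ml of Kdo2-lipid A (KLA), the lipid A core of lipopolysaccharide and an agonist of Toll-like receptor 4. The treatment lasted 1 hr, and in RNA-Seq also 4 hr. ChIP-Seq measured binding of PU.1 and C/EBPa, which are lineage transcription factors of macrophages, of the NF-kB subunit p65, and the histone marks H3K4me2 and H3K27Ac, which lie at promoters and enhancers. GRO-Seq measured RNA still attached to the polymerase, and RNA-Seq measured polyadenylated RNA. Of the 40 samples of the series, 30 were used, and the other 10 (input DNA, CB6F1/J F1 Hybrids and NOD/ShiLtJ) were not analysed here. There was 1 library for each strain, treatment and assay, except p65 after KLA with 2 replicates per strain. The labels do not say whether libraries came from separate animals, so all p-values measure only the spread between these libraries, which may be technical.

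Reads were aligned with Bowtie 0.12.7 and processed with HOMER on build mm9, per the submitters' processing notes. The expression table of the authors holds 29028 RefSeq transcripts with log2 values, deposited as the logarithm of 1 plus the exon tags per 10 M tags of the library (M, mega), per the file headers. The values are not corrected for transcript length. On the linear scale they are whole tags plus an evenly spread random part with a mean near 0.5 tag, seen as steps at whole tags, and taking the whole part recovers the tags. Of the rows, 21 had no symbol and were left out. The others gave 22865 genes, each represented by the transcript with the highest mean over the RNA-Seq libraries, and 332 of these genes have more than 1 genomic copy in the table. Whether tags were assigned by strand is not given in the sources used here, so tags of overlapping genes, and of close relatives such as the Ifi200, Gbp and H2-Q genes and clustered zinc finger genes, cannot be fully told apart.

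Peaks and regions were called with HOMER on each sample alone against an input library, per the file headers. A peak needed 4-fold more tags than the input and than its 10000 bp surroundings, and an FDR of 0.001, as set in the headers. H3K27Ac lists nevertheless hold regions listed with 0 tags, 5 and 1 in C57BL6/J without treatment and after KLA and 2 in BALBc/J without treatment, and these were kept. The tag signal of a peak was deposited by the authors as tags per 10 M and is the peak's own value, listed only where a peak was called. Factor peaks are 200 bp wide and histone regions were stitched to variable length. The header of the C57BL6/J untreated H3K4me2 list names no region size, unlike the other H3K4me2 lists. Both BALBc/J p65 lists were called against the C57BL6/J input, per the file headers. Coordinates are those of the files, on mm9, and no mm9 genome sequence was used here.

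Depth per library came from the file headers. RNA-Seq libraries held 17.0 to 20.3 M tags, of which 88.7 to 90.6% lay in exons of the genes used. GRO-Seq libraries held 39.4 to 48.3 M tags, of which 7.38 to 9.83% lay in these exons, so that 3.07 to 4.34 M tags carry the GRO-Seq values. ChIP-Seq libraries held 7.10 to 14.4 M tags.

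Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(tags per 10 M + 10), with Benjamini-Hochberg adjustment. A gene entered when it reached 20 tags per 10 M in at least 2 libraries of the assay, which kept 10715 genes in RNA-Seq and 9121 in GRO-Seq. Each assay was fitted separately with additive terms for treatment and strain. For the KLA contrasts the strains act as the 2 replicates, and for the strain contrasts the treatments do. A gene was called at an adjusted p under 0.05 and a fitted change of at least 1 on the log2 scale. The pseudocount makes the fitted change of low genes smaller than the ratio of their tags. Residual degrees of freedom before moderation were 2 in RNA-Seq and 1 in GRO-Seq. In GRO-Seq the estimated prior degrees of freedom were infinite, so its p-values rest on the spread pooled over genes. Errors beside log2 values are standard errors of this fit. A strain-dependent response has no residual in this design and was given as a difference of responses with no p-value.

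Gene lists were fixed before the data were examined. They covered immediate early genes, inflammatory cytokines and chemokines, NF-kB pathway and feedback, interferon response, macrophage identity, alternative activation, sterol and LXR targets, MHC genes, the Ifi200 family, the SLAM family, glycolysis, cell cycle and reference genes. Further lists held markers of T and NK cells, B cells, neutrophils, eosinophils, mast cells, dendritic cells, mesothelial cells and fibroblasts, and erythroid cells. For each of the 21 lists the median change was placed among 10000 random lists of the same size, drawn for each member from the 200 genes nearest in mean level. Members passing the gene test were counted over all genes tested and adjusted over the list alone. Named genes followed a rule fixed in advance. It took for each contrast the 10 called genes with the largest change in each direction and the same sign in every pair, up to 4 members of each list with the largest change, and 9 genes in every library. For the strain-dependent response it took up to 10 genes whose GRO-Seq difference had the same sign and a size of at least 1. For peaks it took the 3 with most tags per strain and factor that overlapped no peak of the other strain.

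Peak lists were compared by overlap of at least 1 bp, within a treatment and between strains. Shares carry Wilson 95% intervals where given, which cover counting error only. Shares pooled over strains count a shared site in both lists as if independent, so their intervals are too narrow. p65 peaks shared by the 4 lists were tested with limma on log2 tags, 2 libraries against 2, with the same thresholds. Co-occurrence of strain differences of PU.1 and C/EBPa, p65 overlap of regions gained after KLA, and expression near one-strain regions carry 95% intervals from 1000 resamples of the chromosomes, which describe these libraries. The transcription start of a gene was the 5' end of its transcript in the deposited table.

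The procedures were tested on simulated data made from the real means. For expression the spread was assumed, equal for every gene and not taken from the real libraries. The expression values below hold for that spread only. At 4-fold, 100% of the changed genes were called in RNA-Seq KLA 1 hr (10482 genes) and 98.9% in GRO-Seq KLA 1 hr (8714 genes). At 2-fold, 35.7 and 21.1% were called. For the strain contrasts the 2-fold values were 38.9% in RNA-Seq (10465 genes) and 11.7% in GRO-Seq (8724 genes). For p65, simulated with the spread of the real replicates on 36850 peaks, 84% of 4-fold and 16% of 2-fold changes were called. The p65 run held both sizes, with 100 changed peaks each, and made 6 false calls in all. Its noise was independent between libraries, with no shift of a whole library, so the p65 values hold for that setting only. In the real p65 libraries the median log2 difference between strains was 0.32. Deviations of same-numbered libraries correlated at 0.65 across loci. The expression runs made 0 false calls at their assumed spread.

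Alternatives changed 1 choice at a time. For expression they were pseudocounts of 2 and 50, no filter on low values, a filter of 100 tags per 10 M, centring each library on its median, the longest transcript per gene, no threshold on the size of the change, and fewer libraries. For peaks they were the 50% of each list with the most tags, peak centres within 100 bp or an overlap of 50% of the shorter region, p65 peaks from any list, and a wider distance to genes. Added after seeing the data were limma's voom on the recovered whole tags, removal of the random part of each value, and a p65 fit with both centring and the replicate number. Statistics outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.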

Results

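The data comprised 20 ChIP-Seq peak lists, 6 RNA-Seq libraries and 4 GRO-Seq libraries of thioglycollate-elicited peritoneal macrophages from C57BL6/J and BALBc/J mice. The design asks how the strains differ in factor binding, histone marks and transcription, and how each responds to KLA, a Toll-like receptor 4 agonist. RNA-Seq had 3 libraries per strain (no treatment, KLA for 1 hr and KLA for 4 hr) and GRO-Seq had 2 (no treatment and KLA for 1 hr). PU.1, C/EBPa, H3K4me2 and H3K27Ac had 1 list per strain and treatment. Only p65 had replicate libraries, 2 per strain after KLA. PU.1 lists held 67074 to 71158 peaks, C/EBPa lists 40060 to 48147, H3K4me2 lists 55286 to 58154 regions, H3K27Ac lists 25937 to 26992 regions and p65 lists 47616 to 60505 peaks.

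Regulators of the macrophage and of the KLA response were measured in every library. Sfpi1, the gene of PU.1, was at 3595 (C57BL6/J) and 3917 (BALBc/J) RNA-Seq tags per 10 M tags without treatment and at 6449 and 5256 after KLA for 4 hr. Cebpa, the gene of C/EBPa, went from 3145 and 3181 to 364 and 273 over the same time. Tnf, a cytokine made early after Toll-like receptor signalling, rose from 516 and 603 to 81654 and 75374 after 1 hr, and stood at 33116 and 26254 after 4 hr. Il1b, the interleukin 1 beta precursor, was at 225 and 248 without treatment and at 38263 and 28580 after 4 hr. Il6 was at 13.3 and 12.2 without treatment and at 2926 and 1272 after 4 hr. Nfkbia, the inhibitor of NF-kB that its own target factor induces, was at 698 and 704 without treatment and at 42196 and 48102 after 1 hr. Ifnb1, the interferon beta gene, was at 1.3 and 0.5 without treatment, near the limit of detection, at 228 and 596 after 1 hr and at 24.3 and 16.2 after 4 hr. Rela, the gene of p65, was at 1044 and 957 without treatment and at 2348 and 2537 after 4 hr, and Tlr4, the receptor, was at 1001 and 1547 and then at 448 and 526. These levels have no replicate within a strain and treatment.

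**Figure D1:**
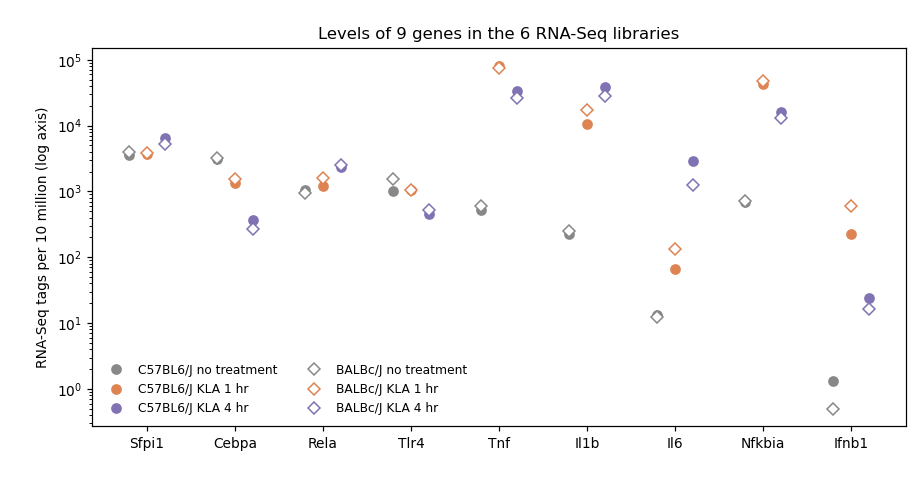
RNA-Seq level (tags per 10 M, log axis) of 9 genes in the 6 libraries, filled circles for C57BL6/J and open diamonds for BALBc/J, with the treatment given by colour. Tnf rose from 516 and 603 to 81654 and 75374 after 1 hr of KLA in the 2 strains.

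After 1 hr of KLA, RNA of cytokines, chemokines and members of the NF-kB inhibitor family rose. The neutrophil-attracting chemokines Cxcl2 and Cxcl1 rose by 7.55 ± 0.25 and 7.31 ± 0.20 on the log2 scale, which is 187-fold for Cxcl2. Cxcl2 lies on chromosome 5 from 91332924 to 91334964. Tnf rose by 7.11 ± 0.18 and Tnfsf9, the ligand of the T cell receptor 4-1BB, by 7.07 ± 0.22. Nfkbiz and Nfkbia, which belong by name to the NF-kB inhibitor family, rose by 6.69 ± 0.17 and 5.99 ± 0.17. Il1b, the chemokine Ccl4, Il1a and the immediate early transcription factor Egr1 rose by 5.78, 5.56, 5.13 and 5.67. The genes that fell most were Arrdc3, an arrestin-like adaptor of membrane receptors (-2.47 ± 0.34), Ier5l (-2.15 ± 0.23), 2810008D09Rik (-2.15 ± 0.24) and the vesicle fusion protein gene Vamp1 (-1.98 ± 0.21). Zinc finger genes made up the rest of the 10, namely Zfp319 (-2.15 ± 0.22), Zfp472 (-2.11 ± 0.19), Zfp87 (-1.97 ± 0.19), Zfp748 (-1.94 ± 0.19), Zfp763 (-1.91 ± 0.27) and Zbtb39 (-1.85 ± 0.25).

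In this contrast 195 genes were higher and 155 lower of 10715 tested with limma, every called gene with the same sign in both strains. The median of all genes was -0.21, and relative to it (libraries centred on their medians) 242 genes were higher and 77 lower. The changes of Arrdc3 and Zfp319 relative to the median gene were -2.25 and -1.93. The lower genes were the less firm part. Their count was 38 with a pseudocount of 50, 32 without a filter and 76 with the stricter filter, and the calls of Vamp1 and Zfp763 (pseudocount 50) and of Arrdc3, Zbtb39 and Zfp763 (no filter) ended there.

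Among the lists, 18 of 20 tested immediate early genes rose at 1 hr, 18 also when adjusted over the list alone, none fell and the median was 2.78. Examples besides Egr1 were the phosphatase gene Dusp1 (4.79 ± 0.17), the RNA-destabilising factor Zfp36 (4.11 ± 0.16) and the AP-1 subunit Fos (3.93 ± 0.18). Of 28 cytokines and chemokines 19 rose, 22 when adjusted over the list alone, and the median was 2.26. Of 23 genes of the NF-kB pathway and its feedback 17 rose, 17 adjusted over the list alone, with a median of 1.90, including the signalling inhibitor Socs3 (4.34 ± 0.18) and the deubiquitinase Tnfaip3 (4.34 ± 0.19). Of 31 interferon response genes 4 rose, 6 adjusted over the list alone and 8 relative to the median gene. These 4 were Ifnb1 (5.12 ± 0.38), the transcription factor Irf1 (3.65 ± 0.23), the ubiquitin-like modifier Isg15 (2.53 ± 0.37) and the GTPase Gbp5 (2.01 ± 0.19). The medians of these 4 lists lay at the 100 percentile of matched random lists.

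Other lists had at most 1 call in each direction at 1 hr. Among 24 macrophage identity genes the lipopolysaccharide co-receptor Cd14 rose (2.77 ± 0.20) and Cebpa fell (-1.13 ± 0.20), 1 each also when adjusted over the list alone, and the call of Cebpa ended relative to the median gene (-0.91). Of 10 alternative activation genes Egr2 rose (3.09 ± 0.21), and of 17 cell cycle genes the proliferation marker Mki67 rose (2.81 ± 0.22), with the same counts when adjusted over the list alone. None of 19 sterol and LXR targets, 18 MHC genes, 9 Ifi200 genes, 8 SLAM genes, 14 glycolysis genes and 9 reference genes was called, with 0 also when adjusted over the list alone. The medians of several of these lists still lay high among matched random lists, with Ifi200 genes at the 100 percentile (median 0.29, 1 gene higher relative to the median gene), alternative activation at 99.8, MHC genes at 99.7 and reference genes at 98.2. Of the markers of other cells, none of 1 T and NK cell, 2 B cell, 3 neutrophil, 1 eosinophil, 4 mast cell, 4 dendritic cell and 10 mesothelial and fibroblast genes was called, 0 when adjusted over the list alone, and no erythroid marker reached the filter. Across all genes limma gave 2480 genes at an unadjusted p under 0.05.

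After 4 hr the genes with the largest increases included antiviral and interferon-induced genes. Irg1, whose enzyme makes the antimicrobial metabolite itaconate, rose by 7.43 ± 0.18 (chromosome 14, 103446228 to 103455790). The GTPase gene Gbp5 rose by 7.41 ± 0.19, and the antiviral genes Ifit1, Ifit2, Mx1 and Rsad2 by 7.35 ± 0.39, 7.26 ± 0.18, 7.19 ± 0.19 and 7.13 ± 0.20. Cmpk2, a mitochondrial nucleotide kinase, rose by 7.26 ± 0.16, the chemokines Ccl5 and Cxcl10 by 7.20 ± 0.32 and 7.19 ± 0.26, and Tnfsf15, a tumour necrosis factor relative, by 7.09 ± 0.22. Among the genes that fell were Fbxo32, a ubiquitin ligase subunit (-5.46 ± 0.17), the cannabinoid receptor gene Cnr2 (-4.93 ± 0.19), the chemokine receptor gene Cxcr4 (-4.67 ± 0.18) and the stress protein gene Sesn1 (-4.28 ± 0.23). Tcp11l2 (-4.15), the Max-binding repressor Mnt (-4.14), the clock gene Per1 (-4.10), Eepd1 (-4.04), the focal adhesion gene Tns1 (-4.04) and Tmem86a (-3.99) fell as well. Fbxo32 and Cnr2 stood at -5.02 and -4.49 relative to the median gene.

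At 4 hr 864 genes were higher and 2262 lower with limma, all with the same sign in both strains. The median of all genes was -0.47. Relative to it the split was 1250 higher and 1023 lower, so that the direction of the excess depended on the scaling. With a pseudocount of 50 there were 1276 lower genes.

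All 31 interferon response genes rose at 4 hr, 31 adjusted over the list alone, with a median of 5.11. All 9 tested Ifi200 genes, which encode DNA sensors and their relatives, rose (9 adjusted over the list alone, median 4.15), including Ifi205 (6.21 ± 0.30) and Mnda (4.54 ± 0.31). Of 28 cytokines and chemokines 26 rose (26 adjusted over the list alone, median 4.79), and of 23 NF-kB genes 22 rose (22 adjusted over the list alone, median 3.13), with the co-stimulatory receptor Cd40 at 6.53 ± 0.26 and the prostaglandin synthase Ptgs2 at 5.58 ± 0.18. Of 18 MHC genes 6 rose (6 adjusted over the list alone), with the peptide transporter gene Tap1 at 3.77 ± 0.17 and the immunoproteasome gene Psmb9 at 2.43 ± 0.19. Immediate early genes split, 3 higher and 4 lower (the same adjusted over the list alone), or 7 and 3 relative to the median gene. Fosb (-2.81 ± 0.21) and Jun (-2.29 ± 0.19) fell in both scalings, and Zfp36 (1.87 ± 0.16) rose.

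Of 24 macrophage identity genes 3 rose and 4 fell at 4 hr, 3 and 4 adjusted over the list alone, or 7 and 2 relative to the median gene. Cebpa (-3.29 ± 0.20) fell, and Cd14 (2.87 ± 0.20) and the Fc receptor gene Fcgr1 (1.99 ± 0.17) rose. Of 10 alternative activation genes 3 rose and 4 fell, or 3 and 1 relative to the median gene, with the transglutaminase Tgm2 at 1.52 ± 0.17. Of 19 sterol and LXR targets 4 fell and none rose (4 lower and 2 higher relative to the median gene), with the cholesterol exporter Abcg1 at -2.16 ± 0.17 and the sterol reductase Dhcr7 at -2.08 ± 0.21. Of 8 SLAM genes 3 rose and 1 fell, with Slamf1, a lymphocyte activation receptor, at 3.78 ± 0.41, and Cd84 (-1.08 ± 0.18) not called relative to the median gene. Of 14 glycolysis genes 4 rose and 1 fell, with the hexokinase gene Hk2 at 1.73 ± 0.20 and Pfkl at -1.50 ± 0.19. Of 17 cell cycle genes 2 rose (the cyclin gene Ccnd2 at 5.68 ± 0.19 and Mki67 at 2.30 ± 0.22) and 1 fell, Mcm2 at -1.72 ± 0.22. Counts adjusted over the list alone were the same for each of these lists.

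Markers of other cells and reference genes were also followed at 4 hr. The T cell kinase gene Lck rose (3.63 ± 0.20), as did the neutrophil marker S100a8 (1.08 ± 0.20) and the dendritic cell marker Ccr7 (1.68 ± 0.21). Of the mast cell markers the histamine-making Hdc rose (4.13 ± 0.19) and Cpa3 fell (-1.24 ± 0.20), a call that ended relative to the median gene (-0.80). None of 2 B cell, 1 eosinophil and 10 mesothelial and fibroblast markers was called, with 0 also when adjusted over the list alone. Of 9 reference genes, the actin gene Actb rose (1.22 ± 0.19, or 1.65 relative to the median gene). Counts adjusted over the list alone were the same for these lists.

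**Figure D2:**
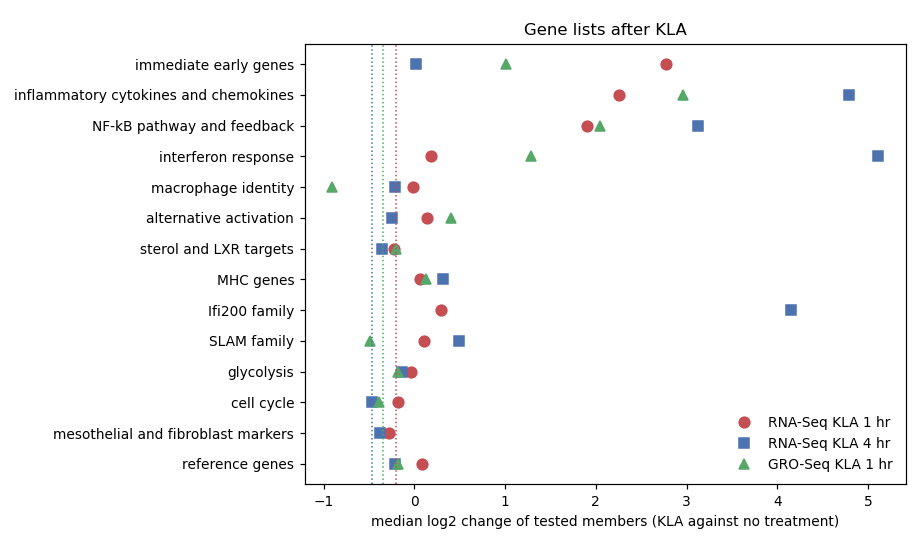
Median log2 change after KLA of the tested members of each gene list with at least 8 members tested in RNA-Seq (horizontal axis, log2), for RNA-Seq at 1 hr and 4 hr and GRO-Seq at 1 hr; a point needs at least 5 tested members, and dotted lines mark the median of all genes. The interferon response list moved from 0.18 at 1 hr to 5.11 at 4 hr in RNA-Seq, and stood at 1.28 in GRO-Seq at 1 hr.

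Nascent transcription after 1 hr, measured by GRO-Seq, rose at inflammatory genes. Il1b rose by 6.34 ± 0.33, Irg1 by 5.87 ± 0.31, Gbp5 by 5.18 ± 0.35 and Tnfsf9 by 4.86 ± 0.35. Cxcl1, Cxcl2 and Tnf rose by 4.62, 4.23 and 4.21, Ptgs2 by 4.24, the surface proteoglycan gene Sdc4 by 4.25 and Lif, an interleukin 6 family cytokine, by 4.19. Fbxo32 fell most (-4.25 ± 0.34, or -3.89 relative to the median gene), followed by the orphan receptor gene Gpr146 (-3.24 ± 0.36), Fam198b (-3.08 ± 0.36) and Tifab (-2.98 ± 0.35). Arhgap25 (-2.89), Cnr2 (-2.89), the linker histone gene Hist1h1d (-2.87), Bhlha15 (-2.82), Gramd4 (-2.80) and the cadherin gene Cdh23 (-2.75) fell as well.

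In GRO-Seq 391 genes were higher and 1413 lower of 9121 tested with limma, all with the same sign in both strains. The median of all genes was -0.34, and relative to it 619 genes were higher and 638 lower. With a pseudocount of 50 the counts were 221 and 329, and with the stricter filter 258 and 469.

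All 23 tested cytokines and chemokines rose in GRO-Seq (23 adjusted over the list alone, median 2.96), as did 19 of 23 NF-kB genes (19, median 2.05), 12 of 23 interferon response genes (12, median 1.28) and 10 of 19 immediate early genes (10, median 1.01), of which 2 fell and none did relative to the median gene. Examples were the RNA sensor gene Ifih1 (3.89 ± 0.30), Rsad2 (3.31 ± 0.33), Icam1, an adhesion molecule (3.44 ± 0.32), and Dusp1 (2.32 ± 0.29). Of 22 macrophage identity genes 2 rose and 9 fell (2 and 9 adjusted over the list alone, 3 and 7 relative to the median gene), and the list median of -0.90 lay at the 0.01 percentile of matched random lists. Fcgr1 (-2.28 ± 0.29), Tlr4 (-2.07 ± 0.36) and the transcription factor Irf8 (-1.93 ± 0.34) fell, and Cd14 rose (1.95 ± 0.33).

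The remaining lists had few calls in GRO-Seq. Of 19 sterol and LXR targets 5 fell, or 2 relative to the median gene with 1 higher, with Abcg1 at -1.98 ± 0.33. Of 5 alternative activation genes 2 rose and 1 fell, with Tgm2 at 1.86 ± 0.32 and the immune checkpoint ligand Pdcd1lg2 at -1.65 ± 0.25. Of 13 MHC genes H2-Q4 rose (1.24 ± 0.34), and of 5 SLAM genes Cd84 fell (-1.62 ± 0.33). Of 6 cell cycle genes Mki67 (2.56 ± 0.33) and Ccnd2 (2.04 ± 0.34) rose and Mcm2 (-1.37 ± 0.21) fell. Of 15 glycolysis genes Pkm (-1.26 ± 0.28) and Pfkfb3 (-1.15 ± 0.34) fell, but relative to the median gene neither was called and 3 genes of this list were higher. None of 3 Ifi200 genes was called, or 2 higher relative to the median gene, and none of 9 reference genes in either scaling. None of the few tested markers of other cells was called, or 1 T and NK cell marker relative to the median gene. Counts adjusted over the list alone were the same for these lists.

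RNA-Seq and GRO-Seq come from separate libraries, and 8401 genes were tested in both. For KLA at 1 hr, 127 genes were higher in both, against 7.52 for independent lists, and 42 were lower in both against 21.1, with 4 called in opposite directions. Relative to the median gene, 169 were higher and 14 lower in both.

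The genes with the largest strain differences included complement, histocompatibility and interferon-inducible genes. Higher in C57BL6/J were the villin relative Vill (4.02 ± 0.19), the secreted factor Gdf15 (3.68 ± 0.35), the complement C1q chains C1qb (3.51 ± 0.19) and C1qc (2.76 ± 0.16), Lrrc27 (3.16 ± 0.15), Plekhg1 (3.11 ± 0.22), Qpct (3.09 ± 0.15), Vsig8 (2.93 ± 0.18), Gdf3 (2.74 ± 0.17) and Alas1, the first enzyme of haem synthesis (2.68 ± 0.27). Higher in BALBc/J, and so negative, were the Ifi200 gene Ifi202b (-6.47 ± 0.44), H2-Ea-ps, which encodes the alpha chain of the class II E molecule and is listed as a pseudogene (-5.62 ± 0.16), the histidine-degrading enzyme gene Hal (-4.94 ± 0.26) and the mitochondrial arginase gene Arg2 (-4.15 ± 0.29). The class I gene H2-Q6 (-4.46 ± 0.18), 2410017I17Rik (-4.47 ± 0.16), the proton pump subunit gene Atp6v0e2 (-4.16 ± 0.18) and the interferon-inducible genes Gbp1 (-4.74 ± 0.90), H28 (-4.66 ± 0.73) and Ifi44 (-3.89 ± 0.26) followed. Ifi202b lies on chromosome 1 from 175892699 to 175912975 and H2-Ea-ps on chromosome 17 from 34479156 to 34481590.

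In RNA-Seq 129 genes were higher in C57BL6/J and 270 higher in BALBc/J with limma, all with the same sign in the 3 treatment pairs. Relative to the median gene the split was 167 and 214. With a pseudocount of 50 it was 60 and 110 and with the stricter filter 72 and 145, and with a pseudocount of 2 there were 407 genes higher in BALBc/J. The differences of Gbp1 and H28 were largest after KLA for 4 hr (-8.28 and -7.51), and both calls ended without a filter on low values.

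**Figure D3:**
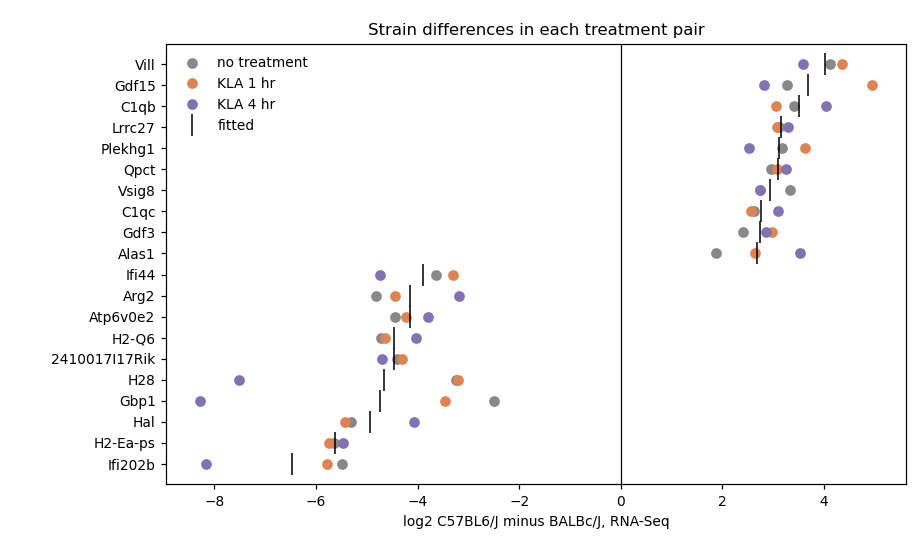
Log2 difference of RNA-Seq level between C57BL6/J and BALBc/J (horizontal axis) for the 20 named genes, with points for the 3 treatment pairs and a bar for the fitted value. All 3 points of each gene lie on the same side of 0, from Vill (fitted 4.02) to Ifi202b (fitted -6.47).

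Most lists had few strain calls in RNA-Seq. Of 18 MHC genes 1 was higher and 3 were lower in C57BL6/J (1 and 3 adjusted over the list alone), with H2-DMb1 at 1.64 ± 0.16 and H2-Q4 at -1.08 ± 0.18, the latter not called relative to the median gene. Of 31 interferon response genes 2 were lower, Ifi44 and the transcription factor Irf7 (-1.03 ± 0.26), 3 adjusted over the list alone and 1 relative to the median gene. The median of this list, -0.31, lay at the 0 percentile of matched random lists, as did that of the mesothelial and fibroblast markers, and cell cycle genes lay at 0.22. At the other end lay sterol and LXR targets (median 0.36) and MHC genes (0.19) at the 100 percentile and SLAM genes at 99.99. Of 9 Ifi200 genes Ifi202b was lower and Mnda higher (1.69 ± 0.25). Of 10 mesothelial and fibroblast markers 4 were lower in C57BL6/J (4 adjusted over the list alone, 3 relative to the median gene, list median -0.86), namely the matrix genes Lum (-1.46 ± 0.21), Col1a1 (-1.21 ± 0.26) and Dcn (-1.06 ± 0.17) and the mesothelial gene Upk3b (-1.38 ± 0.16). Of 24 macrophage identity genes the scavenger receptor gene Marco was higher (2.68 ± 0.21), or 2 genes relative to the median gene. Of 8 SLAM genes Slamf7 was higher (1.50 ± 0.28). Of 19 sterol and LXR targets the exporter gene Abca1 was higher (1.16 ± 0.18) and the lipid transfer gene Pltp lower (-1.38 ± 0.13).

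Of 28 cytokines and chemokines Lif (-1.41 ± 0.17) and Csf3, a granulocyte growth factor (-1.24 ± 0.30), were lower in C57BL6/J. Of 10 alternative activation genes Chi3l3 was higher (1.03 ± 0.16) and the chemokine Ccl24 lower (-1.62 ± 0.36). Relative to the median gene 3 of this list were higher and 1 lower, and its median lay at the 99.2 percentile. Of 4 mast cell markers the tryptase gene Tpsab1 was lower (-1.81 ± 0.18). Of 9 reference genes 1 was higher and none lower. None of 20 immediate early, 23 NF-kB, 14 glycolysis and 17 cell cycle genes was called, and none of the 1 T and NK cell, 2 B cell, 3 neutrophil, 1 eosinophil and 4 dendritic cell markers. The median of the 3 neutrophil markers was 0.85, at the 100 percentile of matched random lists. Apart from the interferon response list, counts adjusted over the list alone were the same for all lists with a tested member.

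In GRO-Seq, Mid1, a microtubule-associated ubiquitin ligase (3.04 ± 0.32), G530011O06Rik (2.71 ± 0.34), the scaffold gene Ksr2 (2.28 ± 0.31), Mamdc2 (2.15 ± 0.35), Efr3b (2.02 ± 0.32), Slamf8 (1.88 ± 0.36) and Mertk, a receptor for the uptake of dying cells (1.88 ± 0.34), were higher in C57BL6/J. So were Loxl2 (1.70 ± 0.34), the cell fusion gene Dcstamp (1.70 ± 0.32) and Ddhd1 (1.67 ± 0.29). Hal (-3.47 ± 0.36), the calcium channel gene Cacna1a (-2.54 ± 0.33), the adhesion gene Cadm1 (-2.46 ± 0.36), D10Bwg1379e (-2.39 ± 0.27), AI506816 (-2.25 ± 0.22), the protease gene Adamts1 (-2.15 ± 0.30), Ifi202b (-2.13 ± 0.23), the scavenger receptor gene Colec12 (-2.11 ± 0.33), Rasal2 (-1.91 ± 0.35) and Ndrg1 (-1.85 ± 0.36) were lower. In all, 39 genes were higher and 44 lower with limma, or 87 and 28 relative to the median of all genes, which was -0.22. With a pseudocount of 50 the counts were 17 and 10, and the calls of Loxl2, Dcstamp, AI506816 and Ifi202b ended.

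Few list members were called between strains in GRO-Seq. Mrc1, the mannose receptor gene of the alternative activation list (1.32 ± 0.33), Abca1 (1.33 ± 0.27), Slamf8, the neutrophil marker Mmp9 (1.32 ± 0.36) and the integrin gene Itgax of the dendritic cell list (1.19 ± 0.30) were higher in C57BL6/J. H2-Ea-ps (-1.58 ± 0.16) and Ifi202b were lower, and so were the 2 tested fibroblast markers Col1a1 (-1.17 ± 0.26) and Col1a2 (-1.11 ± 0.24), whose calls ended relative to the median gene. No other list had a call over all genes; adjusted over the list alone, 1 sterol gene was lower and the SLAM list had 2 higher. Of the strain differences, 21 genes were higher in C57BL6/J in both assays against 0.33 for independent lists, 25 were lower in both against 0.43, and none went in opposite directions. Relative to the median gene these counts were 39 and 21.

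The response to KLA at 1 hr could differ between strains only as a value, with no test in this design. In RNA-Seq 25 genes differed in their response by at least 1, of which 16 had the more positive change in C57BL6/J and 9 in BALBc/J. In GRO-Seq 18 of the 25 had the same sign, which is 72% (95% exact binomial interval 50.6 to 87.9). The GRO-Seq difference was below 0 in 90.5% of all genes, so that 38.7% would share the sign if the assays were unrelated. The sign was shared by 10 of the 16 genes with the more positive change in C57BL6/J. It was shared by 8 of the 9 with the more positive change in BALBc/J (88.9%), close to the 90.5% of all genes. Relative to the median difference of all genes in each assay, which was -0.44 in GRO-Seq, it was 15 of 25, or 60%, and with libraries centred on their medians 54.2% of 24 genes. The share was 43.8% of 64 genes with a pseudocount of 2, 90% of 10 genes with one of 50 and 50% of 8 genes with the stricter filter. Only 3 genes reached 1 in both assays with the same sign. Niacr1, the niacin receptor gene, had a difference of -1.50 in RNA-Seq and -1.08 in GRO-Seq. Hbegf, a growth factor of the epidermal growth factor family, had -1.24 and -1.28, and the small nucleolar RNA gene Snord2 had 1.04 and 2.06. Relative to the median difference the GRO-Seq values were -0.63, -0.84 and 2.51, so only Snord2 stayed above a size of 1. At 4 hr their differences were -0.57, -0.27 and 0.33.

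PU.1 and C/EBPa binding and both histone marks were mostly shared between strains. Without treatment, 82.1% of the C57BL6/J and 78.5% of the BALBc/J PU.1 peaks overlapped a peak of the other strain, and after KLA 79.0 and 77.0% did. For C/EBPa the shares were 83.2 and 69.2% without treatment and 77.0 and 75.0% after KLA. The immunoprecipitation efficiencies of these C/EBPa libraries were 17.8 and 24.7% without treatment and 20.8 and 21.4% after KLA. Yield and strain were not told apart there. H3K4me2 regions overlapped at 86.9 and 87.0% and at 89.3 and 85.1%, and H3K27Ac regions at 81.5 and 81.7% and at 80.2 and 79.5%. Pooled over strains the untreated shares were 80.2% for PU.1 (Wilson interval 80.0 to 80.5) and 75.6% for C/EBPa (75.3 to 75.9). Peaks in one strain were weaker. PU.1 peaks of untreated C57BL6/J had a median of 18 tags per 10 M where BALBc/J had none and 47 where it had one.

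The p65 replicates give the only measured replicate error of an overlap. Replicates of C57BL6/J overlapped at 83.8 and 84.0% and those of BALBc/J at 72.7 and 87.0%, while lists of different strains overlapped at 67.5 to 88.0%. Pooled, the shares were 81.7% within and 78.1% between strains. In the 50% of each list with the most tags, 92.6 to 99.1% of peaks were found in the other list over all factors and marks.

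**Figure D4:**
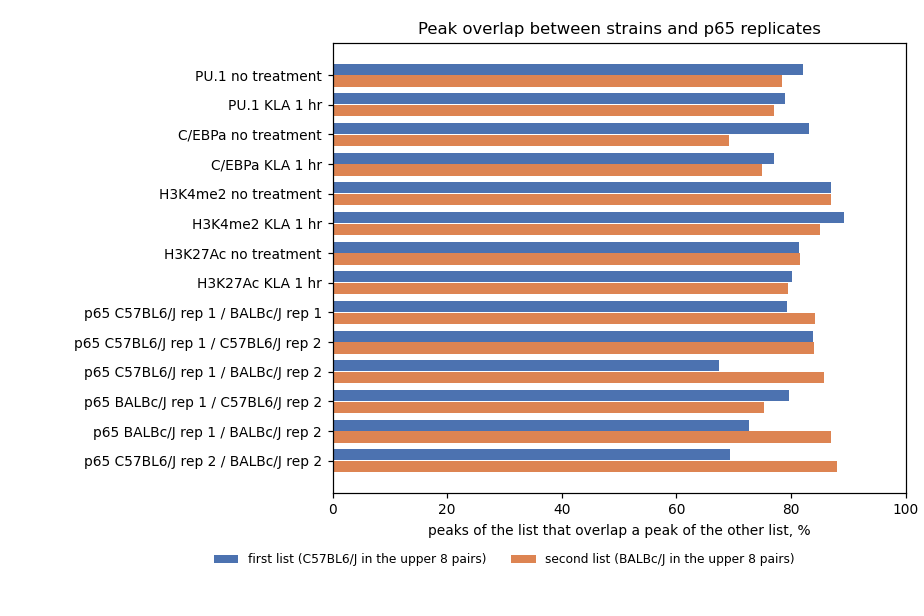
Percent of the peaks of each list that overlap a peak of the other list by at least 1 bp, for C57BL6/J against BALBc/J in the upper 8 pairs and for each pair of p65 libraries in the lower 6. The p65 replicates of C57BL6/J overlap at 83.8 and 84.0% and lists of different strains at 67.5 to 88.0%.

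The strongest one-strain peaks were placed by the nearest transcription start on mm9. For PU.1 the strongest in C57BL6/J lay on chromosome 8 from 36199820 to 36200020, outside genes and 171176 bp upstream of Tnks, a poly-ADP-ribose polymerase gene, with 280.7 tags per 10 M. In BALBc/J it lay on chromosome 11 from 3093121 to 3093321 inside Sfi1, a centrosome gene, 245 bp from its start, with 326.4 tags. An H3K4me2 region of BALBc/J lay at the same place (3092395 to 3094587, 1922.5 tags). For C/EBPa the strongest was on chromosome 11 from 29618663 to 29618863 inside the reticulon gene Rtn4 in C57BL6/J (254.5 tags). In BALBc/J it was on chromosome 13 from 56454847 to 56455047, 57035 bp upstream of the chemokine gene Cxcl14 (317.4 tags), only 27 bp from a C57BL6/J peak. For H3K27Ac the strongest in C57BL6/J was on chromosome 17 from 31969375 to 31974182, 20958 bp downstream of the start of the kinase gene Sik1 (1151.5 tags). In BALBc/J it was on chromosome 8 from 124677902 to 124682318, 125930 bp upstream of the cofactor gene Zfpm1 (621.9 tags). Overlapping regions of the same strain after KLA had 123.2 and 41 tags. Many untreated peaks in neither list of the other strain were not found after KLA in their own strain. The shares found again were 35.2% (C57BL6/J) and 37.8% (BALBc/J) for PU.1 and 29.3 and 29.1% for C/EBPa. They were 49.8 and 59.7% for H3K4me2 and 18.0 and 22.6% for H3K27Ac. Treatment and library were not told apart there.

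For p65 the strongest locus in both C57BL6/J libraries and neither BALBc/J library lay inside the cell cycle kinase gene Cdk6 on chromosome 5 from 3356052 to 3356255, with 481.6 and 579.6 tags. It was 13 bp from a BALBc/J peak at 3355837 to 3356039, which is itself among the strongest BALBc/J loci (474.1 and 425.5 tags). The strongest BALBc/J locus, on chromosome 13 from 44416489 to 44416694, lay 21 bp from a C57BL6/J peak. In these cases the peaks of the strains lie side by side.

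p65 binding was tested at the 36850 loci found in all 4 lists, of 78777 in all. With limma 594 loci were higher in C57BL6/J and 225 higher in BALBc/J, and 4906 had an unadjusted p under 0.05. With each library centred on its median the split was 127 and 242, so the direction of the excess depended on the scaling. Fewer loci were called without either C57BL6/J library, and more were called higher without BALBc/J replicate 1. Leaving out 1 library at a time gave a median log2 difference of 0.16 to 0.49, against 0.32 with all 4. The lone library of a strain is then assumed to vary like the others. By presence, 5327 loci were in both C57BL6/J lists and neither BALBc/J list and 1910 in the reverse pattern, 7237 in all. The other ways of pairing the 4 lists gave 4937 loci by replicate number and 1380 crossed.

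Strain differences of PU.1 and C/EBPa coincided at a minority of loci, more often than at loci with a shared PU.1 peak. Of loci bound by both factors without treatment, 29.4% of those whose PU.1 peak was found in C57BL6/J only also had a C/EBPa peak found in C57BL6/J only, against 11.7% of those with a shared PU.1 peak, an odds ratio of 3.16 (2.84 to 3.54). In BALBc/J the shares were 43.4 and 20.9%, an odds ratio of 2.90 (2.64 to 3.18). In the KLA lists the odds ratios were 2.57 (2.33 to 2.83) and 2.64 (2.43 to 2.84). Restricted to the 50% of peaks with the most tags they were 14.4 and 8.86.

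PU.1 and C/EBPa peaks gained after KLA in both strains overlapped p65 more often than peaks kept in both conditions. For PU.1, 51.7% of 5289 gained peaks overlapped a p65 peak found in all 4 lists against 35.2% of kept peaks, a difference of 16.5 points (15.3 to 17.8). For C/EBPa it was 67.4 against 53.6%, or 13.8 points (12.6 to 15.0). Peaks lost after KLA in both strains overlapped p65 at 5.79% for PU.1 and 11.6% for C/EBPa. Taking each strain by itself, with peaks gained in both strains included, the differences were 0.08 points (-0.81 to 0.97) for PU.1 in C57BL6/J and -0.17 (-0.99 to 0.70) in BALBc/J. For C/EBPa they were -1.10 (-2.24 to 0.01) and 1.45 (0.57 to 2.30). H3K27Ac regions gained in C57BL6/J overlapped p65 less often than kept ones (41.2 against 56.8%, -15.6 points, -17.5 to -13.9), and in BALBc/J by -11.0 points (-12.9 to -9.16). In both strains the H3K27Ac difference was 0.58 points (-1.77 to 3.19), and H3K4me2 regions gained in both strains differed by -19.1 points (-23.7 to -14.8). Within each strain, gained H3K4me2 regions had medians of 21.7 (C57BL6/J) and 21.2 (BALBc/J) tags per 10 M, against 182.1 and 181.7 in kept ones. For H3K27Ac these were 26.4 and 24.3 against 85 and 78.1. Tags and region length were not matched, and the alternatives that follow were not run for H3K4me2. With presence judged from the 50% of peaks with the most tags the H3K27Ac differences turned to 14.5 points in C57BL6/J and 18.6 in BALBc/J. Those of PU.1 were then 18.3 and 19.4 points and those of C/EBPa 13.2 and 15.4. With p65 peaks of any list the C/EBPa difference in BALBc/J turned to -1.43, that of H3K27Ac in both strains to -14.5 and that of PU.1 in C57BL6/J to -5.24, and that of PU.1 in BALBc/J was -4.94.

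Genes near one-strain H3K27Ac regions differed slightly between strains in the direction of the region, relative to other genes. In RNA-Seq without treatment, 979 genes with a start within 10 kb of a region found in C57BL6/J only had a median strain difference of 0.01 and 1100 genes near a BALBc/J region had -0.15. Genes near neither kind of region had -0.10, and the difference between the C57BL6/J and BALBc/J groups was 0.15 (0.12 to 0.20). In GRO-Seq it was 0.12 (0.07 to 0.15). Near one-strain PU.1 peaks it was 0.06 (0.04 to 0.08) in RNA-Seq and 0.06 (0.03 to 0.08) in GRO-Seq. In RNA-Seq the genes near BALBc/J PU.1 peaks had -0.11, close to the -0.10 of genes near neither. Those near C57BL6/J PU.1 peaks had -0.05. For H3K27Ac the differences were 0.48 and 0.38 when presence was judged from the 50% of regions with the most tags.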

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

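The tests of exon share, immunoprecipitation yield and read mapping, and the splits of the libraries, were chosen only after the results were seen; those of tag share, calling threshold and neighbouring summits were fixed before.

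Responses to KLA at 1 hr of different sign in the strains drew attention at a pair of genes, and the difference was not tested. Hbegf changed by -0.37 in C57BL6/J and 0.91 in BALBc/J in GRO-Seq, a difference of -1.28, while both strains were above 0 in RNA-Seq. The median gene changed by -0.57 in C57BL6/J, so relative to it Hbegf did not decrease there, and the difference relative to the median was -0.84. Snord2 changed by 0.89 and -0.15 in RNA-Seq (difference 1.04) and by 1.52 and -0.54 in GRO-Seq (difference 2.06). Snord2 had at most 24.3 tags per 10 M in these RNA-Seq libraries.

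Responses of opposite sign at 1 hr and 4 hr drew attention at 12 genes, which were higher at 1 hr and lower at 4 hr than without treatment. Among them were Fos, Nr4a1, Gdf15, Egr2, Trib1, Hilpda, Dusp8, Fabp4, Jun, Fosb and Chka. The difference between the times, tested with limma, lay between -6.49 (Nr4a1) and -2.44 (Chka), each with an adjusted p of 8.4e-05 or less. These genes were picked by their calls at both times, so a large negative difference was set by that choice. The p-values add no separate support. The transcription factor genes Fos and Nr4a1 went from 3.93 and 3.91 at 1 hr to -1.20 and -2.58 at 4 hr. Relative to the median gene 8 of the 12 kept both calls, with Nr4a1 at -2.15 at 4 hr. Fos (-0.76), Gdf15 (-0.99), Hilpda (-0.99) and Chka (-0.995) were then not called lower at 4 hr.

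More genes fell than rose after KLA, at 4 hr in RNA-Seq and at 1 hr in GRO-Seq. In RNA-Seq a larger share of the tags going to the genes called higher is a candidate explanation. These 864 genes went from 3.92 to 29.0% of exon tags in C57BL6/J and from 4.23 to 29.9% in BALBc/J. This predicted at least 92.3% of the median shift of all genes. The prediction cannot decide, since values are shares of the tags and a real decrease of the other genes would give the same match. In GRO-Seq a lower exon share may account for part, since in C57BL6/J it went from 9.83 to 7.38% with a median change of -0.57. In BALBc/J the exon share was 8.98 and 9.00% and the median still lay at -0.104, so what is left in that strain cannot be told apart from a small general decrease. A biological decrease of transcription after KLA stays open, as untested.

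The excess of p65 loci with more tags in C57BL6/J may come from a lower immunoprecipitation yield in BALBc/J, whose libraries had efficiencies of 44.8 and 36.8% against 50.4 and 53.3%. Without the BALBc/J library of lowest efficiency 71.3% of the called loci were still higher in C57BL6/J, against 72.5% with all 4. The remaining BALBc/J library is itself below both C57BL6/J libraries, so yield and strain cannot be told apart here. With each library centred on its median the excess turned around, with 127 loci higher and 242 lower in C57BL6/J. Both BALBc/J lists were called against the C57BL6/J input, and a strain difference in binding stays open, as untested.

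Peaks found in one strain only were weighed with untreated PU.1. Peaks near the calling threshold are a candidate explanation for most of them: 19.8% of all peaks were in one strain only, and 4.00% of the 50% with the most tags. Neighbouring summits called apart could account for at most 24.5%, those with a peak of the other strain within 1000 bp, and how many of these are the same site is open. The loss of whole BALBc/J peaks, through reads failing to map to the C57BL6/J reference, cannot produce peaks in BALBc/J only. These were 55.6% of the one-strain peaks. Whether partly failed mapping shifted the place of BALBc/J peaks was not tested. For peaks in C57BL6/J only, failed mapping cannot be told apart. Their share was 43.8% in the 25% of genome bins with most one-strain C/EBPa peaks and 46.0% in the 25% with fewest. The difference was -2.17 points (SE 0.91), where failed mapping predicted a higher share. However, these bins stand in for sequence differences that no variant list checked.

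For the 399 genes called between strains in RNA-Seq, the 6 libraries allow 10 splits of 3 against 3, which cannot give a share under 0.05. The real split gave 399 genes, matched by 1 split (itself), and the highest of the others gave 0. Of the other splits only 3 hold 1 library of each treatment on both sides. All the other splits mix the strains within a side, so strain differences enter their residual. Few calls were then likely whatever the cause, and their 0 does not bear on it.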

How the results depend on the processing

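Tests of voom on recovered tags, of values without their random part and of the block with centring were chosen after seeing the data. Of the values that answer a comparison, 91 kept their direction and stayed within their spread or within 1.5 times their count, 102 moved and 3 reversed; unless stated, the cause was not tested. A change of sign counts as reversed only where the main interval excluded 0. Another 4 differences, whose main intervals included 0, changed sign and are counted as moved. Counts of higher and of lower genes or loci were each scored alone, as kept or moved only. A turn in which of them is larger is therefore not among the 3 reversals. Among such turns, centring gave 1250 higher and 1023 lower in RNA-Seq KLA 4 hr. Between strains it gave 87 and 28 in GRO-Seq and 127 and 242 for p65. For the genes named by contrast, 974 comparisons kept direction and call, 11 lost the call and none reversed. GRO-Seq exons held 3.07 to 4.34 M tags per library, and there the simulation, with its assumed spread, called 21.1% of 2-fold changes after KLA.

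With a pseudocount of 50, which shrinks changes of low genes by construction, lower genes went to 38 (RNA-Seq KLA 1 hr), 1276 (4 hr) and 329 (GRO-Seq KLA), and GRO-Seq higher genes to 221. Strain calls went to 60 higher and 110 lower in RNA-Seq and to 17 and 10 in GRO-Seq. Strain-dependent genes went to 10 with 90% of one sign, and the H3K27Ac expression differences to 0.114 (RNA-Seq) and 0.0688 (GRO-Seq). With a pseudocount of 2, strain calls in RNA-Seq rose to 407 lower, and strain-dependent genes to 64 with 43.8% of one sign. Without a filter, lower genes at KLA 1 hr went to 32 and GRO-Seq strain calls to 88 lower. With the filter of 100, which tests fewer genes, lower genes at KLA 1 hr went to 76, GRO-Seq KLA calls to 258 higher and 469 lower, RNA-Seq strain calls to 72 and 145, GRO-Seq strain calls to 15 and 11, and strain-dependent genes to 8 with 50% of one sign.

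With libraries centred on their medians, lower genes went to 77 (KLA 1 hr) and 1023 (4 hr), GRO-Seq KLA calls to 619 higher and 638 lower and GRO-Seq strain calls to 87 and 28. With no threshold on the change, lower genes went to 237 and 4790 in RNA-Seq KLA, and RNA-Seq strain calls to 302 and 646. With voom on recovered tags, lower strain calls went to 425 in RNA-Seq and 67 in GRO-Seq.

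With the 50% of each list with most tags against the whole of the other, shares between strains were 96.0 and 95.01% for PU.1 (no treatment, KLA), 94.2 and 94.1% for C/EBPa, 99.1 and 99.1% for H3K4me2, 98.0 and 97.7% for H3K27Ac, and 92.6% for p65 (94.7% within a strain). With both lists so reduced they were 86.3 and 84.9%, 81.3 and 82.1%, 90.4 and 90.3%, 85.1 and 85.0%, and 80.9% (84.1%). With stricter overlap, which removes matches by construction, they were 79.3 and 76.7%, 73.9 and 74.1%, 80.3 and 80.5%, 79.7 and 77.9%, and 77.5% (81.1%). Leaving out p65 replicate 1 or 2 of both strains gave 77.6 to 81.7% between strains.

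With the replicate number as a block, p65 loci went to 2401 higher and 531 lower in C57BL6/J. Deviations of same-numbered libraries correlated at 0.65 across loci, but 2 pairs do not show that the numbers pair the samples. With the block and centring the counts were 734 and 1174, and with centring alone 127 were higher. Leaving out 1 p65 library gave 78 to 856 higher and 59 to 220 lower. In RNA-Seq and GRO-Seq the additive terms already make the contrasts paired, by strain for KLA and by treatment for strain.

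Co-occurrence odds ratios were 14.4 (C57BL6/J) and 8.86 (BALBc/J) with the 50% of peaks with most tags, 2.67 and 2.56 with centres within 100 bp, and 2.57 and 2.64 in the KLA lists. For gained regions and p65, in the order C57BL6/J, BALBc/J and both strains, presence from the 50% with most tags gave 14.5, 18.6 (both reversed) and 20.4 points for H3K27Ac, 18.3, 19.4 and 28.3 for PU.1, and 13.2, 15.4 and 20.1 for C/EBPa. p65 peaks of any list gave -27.4, -23.9 and -14.5 for H3K27Ac, -5.24, -4.94 and 9.31 for PU.1, and -3.22, -1.43 (reversed) and 6.80 for C/EBPa. H3K27Ac expression differences were 0.48 and 0.38 with the 50% of regions with most tags, and 0.11 in RNA-Seq within 50 kb.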

Other observations

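The test of zinc finger genes below was chosen only after the result was seen.

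The factors shared many sites. After KLA, 54.3 and 51.9% of the p65 peaks of the C57BL6/J replicates and 54.0 and 53.5% of those of BALBc/J overlapped a PU.1 peak of the same strain, and 45.6, 43.3, 45.4 and 43.6% overlapped a PU.1 peak already found without treatment. For C/EBPa the shares after KLA were 51.4, 48.3, 53.6 and 54.3%. Of C/EBPa peaks, 54.3% (C57BL6/J) and 52.0% (BALBc/J) overlapped PU.1 without treatment and 48.9 and 49.8% after KLA. At shared PU.1 peaks, tags differed at least 2-fold between strains at 4.52% of peaks without treatment, and between treatments at 10.4% in C57BL6/J and 11.4% in BALBc/J. Between p65 replicates of the same strain it was 6.09% (C57BL6/J) and 12.7% (BALBc/J) of the loci found in all 4 lists. PU.1 had no replicates, so its strain and treatment figures were not told apart from replicate error.

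Peaks in one strain were unevenly spread over the genome. In 417 bins of 5 Mb with at least 100 PU.1 peaks, the one-strain share of untreated PU.1 peaks ran from 16.0% at the 10th to 24.6% at the 90th percentile. The variance was 2.13 times that of counting error with every listed peak taken as independent. A site shared by the strains is listed in both, so this ratio is too high by an amount not measured. The highest bin, on chromosome 13 from 65000001 to 70000000, had 36.3%, and the lowest, on chromosome 3 from 20000001 to 25000000, had 9.22%. Across bins the share had a Spearman correlation of 0.51 with that of PU.1 after KLA, 0.30 with p65, and without treatment 0.23 with C/EBPa, 0.33 with H3K4me2 and 0.14 with H3K27Ac; bins are not independent replicates.

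Zinc finger genes named Zfp were frequent among the genes that fell at KLA 1 hr in RNA-Seq, 42 of 155 against 2.26% of the genes tested (odds ratio 19.2, two-sided Fisher's exact test p = 3.36e-34), while 2 rose. At 4 hr the median change of Zfp genes, -0.58, lay at the 18.2 percentile of matched random lists, and the 155 genes became 38 with a pseudocount of 50 and 32 without a filter. Genes are not independent replicates, and the enrichment was tested on the data in which it was noticed. A hypothesis is that lower transcription at these genes contributes. In the separate GRO-Seq libraries 40 of the 42 were tested, and their median change of -0.75 lay at the 0.14 percentile of matched random lists, which is consistent with it; over all 207 Zfp genes tested in GRO-Seq the median was -0.62. A short RNA half-life may add to the decrease and was not tested.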
